A study of Caenorhabditis elegans with 12 samples.

How the data were processed

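Gene expression was measured in *Caenorhabditis elegans* on 12 one-colour Agilent arrays, 3 for each of 4 groups. The groups were sterile adults labelled nhr-114(RNAi), sterile glp-1(q224ts) adults, wild type adults on *E. coli* OP50 with added tryptophan (Trp), and wild type adults on plain OP50. Per the labels' protocols, synchronised larvae were grown at 25 °C, total RNA was extracted with Trizol, and 0.1 ug of it was amplified and labelled with Cy3. The labels give each array a replicate number, and do not say whether the replicates are separate cultures, so a p-value here measures only the spread between these samples.

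Agilent Feature Extraction 10.7.1.1 read the scans, per the submitters' processing notes. The deposited scanner files hold the intensity of each spot on a linear scale, and the processed signal used here is background-subtracted by that program, per the file headers. The deposited value table holds log2 values of the same 12 arrays. Its scale was found by setting each column against the log2 processed signal of its array, where the correlation over 55545 probes lay between 0.995 and 1.000. The median of a column was 7.30 in each of the 12 arrays, so the columns share 1 level and the correction that made them so is not stated. The array design was annotated on the ce4 genome, WormBase release 170, per the file headers. Sequence names on the array were paired with symbols through a table of the WBcel235 reference, used for names only: 19643 of 20081 sequence names matched, and the other 438 keep the name in the files. No coordinates are given, because no genome came with the design's build.

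Each array was put on the log2 scale and shifted so that its 75th percentile over non-control spots was 0. Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged. A probe was kept when its signal was well above background on every array of at least 1 group of the comparison, which left 38369 probes of 14773 genes for the arrays labelled nhr-114(RNAi) against glp-1(q224ts) and 40295 probes of 15562 genes for Trp. The kept probe with the highest mean stood for its gene. Of 6294 called genes with 2 or 3 kept probes in the first comparison, 6244 had probes of 1 sign. Each comparison had its own fit, since the design text describes them as made independently. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) gave log2 fold changes with standard errors (SE), and p-values were adjusted by Benjamini and Hochberg over genes with a threshold of 0.05. Every adjusted p for a gene comes from limma, and ± is an SE unless SD is written.

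A gene whose probe was not well above background on any array of 1 group has only a bound there. Its fold is written as at least N-fold: the mean of the bright group against the mean, per array, of the higher of the lowest signal well above background and the gene's own. Such genes are not ranked. A gene well above background on at least 1 array of each group counts as measured in both and keeps its fitted value. Where it was not so on all 6 arrays, that value rests in part on signal near background. Of 110 called genes named for the first comparison, 64 had a probe well above background on all 6 arrays. In the first comparison 829 called genes were below background in glp-1(q224ts) and 149 in the arrays labelled nhr-114(RNAi). The median log2 fold change over all genes there was -0.27, so changes of genes and lists in that comparison are given relative to this median gene. The limma p-values and calls of genes test the change before this shift. Log2 changes and medians under alternative settings are given as fitted, without the shift. With Trp the median was -0.061 and nothing was subtracted.

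Gene lists (34) were fixed before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. camera was repeated with an estimated correlation, and fry was run beside it. fry's directional p asks whether a list's genes move one way on balance and does not compare them with other genes. The rule for named genes was fixed before the data were examined. It took nhr-114 and glp-1, the 6 largest rises and 6 largest falls among called genes with a symbol whose groups did not overlap, up to 3 called members per list by size, or the member with the smallest p where none was called, and up to 5 genes called in both comparisons per pair of directions. Because the 6 rises this rule took by fitted value were all bounds, which carry no rank, the 6 largest rises measured in both groups were added after values were seen. Members of families with near-identical copies (msp, his, col and other numbered families) can share signal on a probe, and their single values are uncertain.

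All 6 arrays of a comparison shared 1 slide and 1 scan, so slide and scan divide no comparison. The arrays labelled nhr-114(RNAi) and the wild type arrays lay in row 1 of their slides and the other groups in row 2, so array row and group cannot be told apart within a comparison. Between 60.5% and 77.7% of the non-control spots of an array were well above background, and no spot was saturated. The number of arrays limits the precision: the median SE of a log2 fold change was 0.20 in the first comparison and 0.24 with Trp.

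The fit and the list test were tried on simulated gene values, in 1 draw per comparison, with 200 changed genes. Each gene had its real mean and normal noise of the spread limma estimated for it, equal in both groups. Real groups differed in spread, with r between arrays of 0.944 to 0.978 labelled nhr-114(RNAi) and 0.989 to 0.995 in glp-1(q224ts). Scaling, the filter and the choice of probe were not part of the simulation. At log2 changes of 1, 2 and 3 the fit recovered 26.9%, 94.0% and 98.5% of the changed genes in the first comparison, with 4 false calls over 14773 genes. With Trp the shares were 23.9%, 95.5% and 98.5%, with 10 false calls over 15562 genes. In each simulation the 1 list that had been changed was the 1 list called. Simulated genes varied independently of each other, unlike real genes of a list. The simulation therefore does not test the list calls, or the false calls, under correlation between genes.

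Alternatives planned before the data were examined were normexp background correction (offset 50), quantile normalization, the median of each array, the authors' value table, no filter on dim probes, well above background on all 6 arrays, the mean of a gene's probes, all 12 arrays in 1 fit, the replicate number as a block, eBayes with trend, a fold threshold of 2, and leaving out each array in turn. normexp used the median spot signal, since the files carry no mean signal. Alternatives added after seeing the data set the median gene at 0, or set the intestine, body wall muscle, pharynx and neuron markers at 0 on each array. matplotlib 3.10.9 drew the plots.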

Results

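Expression was profiled in 12 arrays of adult *C. elegans* grown at 25 °C, 3 arrays in each of 4 groups. nhr-114 encodes a nuclear hormone receptor, and the labels of 1 group name RNA interference against it and sterile animals. glp-1 encodes the Notch receptor that keeps germline stem cells dividing, and animals with the temperature-sensitive q224ts allele are sterile at this temperature because they make almost no germ cells. The other groups were wild type animals with and without tryptophan added to the bacterial diet. The first comparison sets the arrays labelled nhr-114(RNAi) against glp-1(q224ts), and the second sets wild type animals with added tryptophan against wild type animals without it. Spots well above background made up 63.3 to 71.8% of an array in the arrays labelled nhr-114(RNAi), 60.5 to 65.5% in glp-1(q224ts), 69.5 to 77.7% with Trp and 71.0 to 75.1% in wild type. Arrays of 1 group correlated across genes at r of 0.944 to 0.978 in the arrays labelled nhr-114(RNAi), 0.989 to 0.995 in glp-1(q224ts), 0.969 to 0.991 with Trp and 0.984 to 0.994 in wild type.

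nhr-114 itself was higher, not lower, in the arrays labelled nhr-114(RNAi) than in glp-1(q224ts). Its log2 difference was 2.80 ± 0.61 (SE, n = 3 arrays per group, limma adjusted p = 0.0108), or 3.07 relative to the median gene. Relative to the 75th percentile of its array, the gene's brightest probe read 2.64, 0.047 and 1.65 in replicates 1, 2 and 3 labelled nhr-114(RNAi) and -1.15, -1.36 and -1.56 in glp-1(q224ts). The 3 probes of nhr-114 gave log2 differences of 2.84, 2.81 and 2.80. Which part of the transcript the RNA trigger covered is not stated in the labels. Since the targeted gene goes against the label, these arrays are called "the arrays labelled nhr-114(RNAi)" throughout, and each direction drawn from them rests on that label. The glp-1 gene, which q224ts changes by a point mutation, differed by 0.55 ± 0.28, or 0.82 relative to the median gene. It was not called (limma adjusted p = 0.148), and was called higher in 2 of 18 alternative settings. It belongs to the list of oocyte, eggshell and maternal genes, whose median was 3.79 relative to the median gene, and so rose far less than that list.

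**Figure D1:**
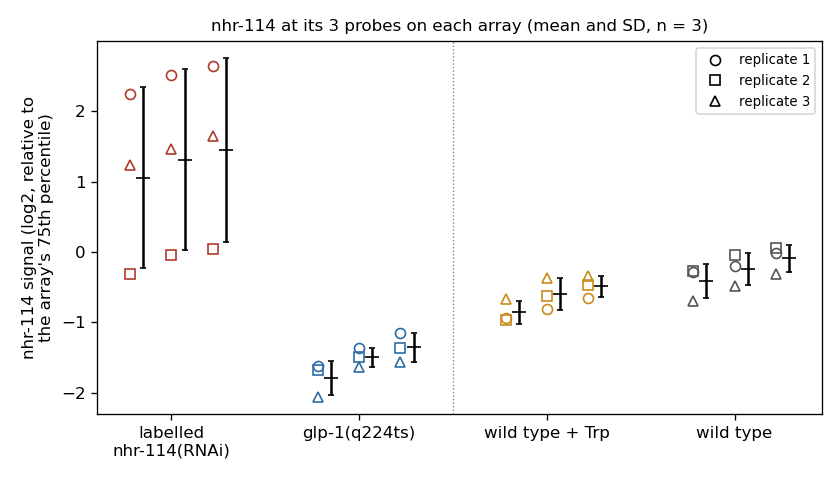
Signal of nhr-114 on each array at its 3 probes, left to right within a group, in log2 units relative to the 75th percentile of the array. Symbols mark replicates, and the black dash and bar give the mean and SD of 3 arrays. The dotted line parts the 2 slides. On the first slide every array labelled nhr-114(RNAi) lies above every glp-1(q224ts) array.

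Germline transcripts were far higher in the arrays labelled nhr-114(RNAi) than in glp-1(q224ts), while cuticle collagens and antimicrobial genes were lower. Relative to the median gene, the median of the germline list was 3.33, that of oocyte and maternal genes 3.79 and that of sperm genes 4.43 on the log2 scale. The cuticle collagens had a median of -0.84 and the antimicrobial and infection-response genes one of -0.84. In all, 3007 genes were higher and 3972 lower (limma, 14773 genes tested, n = 3 per group). At a fold of at least 2 the counts were 2204 and 1490. The groups did not overlap for 9482 genes (64.2%, where chance gives 10%).

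The split between higher and lower depends on the scaling, and called genes are counted at the 75th percentile scale unless another is named. Higher genes made up 43.1% of the calls, 22.6% when the median of each array was the scale (2326 higher, 7956 lower), 33.8% among probes well above background on all 6 arrays (1882 and 3692), 67.2% with the median gene at 0 (3771 and 1837) and 85.7% with the somatic markers at 0 (5450 and 910). The count of lower genes also rests on single glp-1(q224ts) arrays: it was 2078, 2015 and 2502 without replicates 1, 2 and 3.

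The germline program separated the groups most widely. Of the 38 measured genes of germline proliferation, P granules and meiosis, 35 rose, 0 fell and 3 did not pass the test (36 and 0 adjusted over the list alone, 36 and 0 with the median gene at 0). The list was called up (camera adjusted p = 7.32e-17), as were the oocyte and sperm lists (adjusted p = 9.39e-09 and 1.88e-29). With an estimated correlation none of the 34 lists of this comparison was called, and the adjusted p was 0.657 or more for each. The meiotic chromosome axis genes htp-2, htp-3 and him-3 were at least 69.3-fold, 51.9-fold and 71.1-fold higher, since none was well above background in glp-1(q224ts). Of 30 oocyte, eggshell and maternal genes, 25 rose, 1 fell and 4 did not pass the test (25 and 1 adjusted over the list alone, 25 and 1 with the median gene at 0). rme-2, the yolk receptor of oocytes, was at least 232-fold higher, mesp-1 at least 84.9-fold, trcs-1 at least 78.3-fold, the eggshell gene cpg-1 at least 73.4-fold and mex-6 at least 68.3-fold. Of 72 sperm genes, 68 rose, 2 fell and 2 did not pass the test (69 and 2 adjusted over the list alone, 69 and 1 with the median gene at 0), among them msp genes whose copies a probe may not separate. The sperm phosphatase gene gsp-3 was at least 51.9-fold higher, and ssp-33 changed by 5.89 ± 0.35. With bounded genes at their bound, the list medians were 3.26 for germline, 3.79 for oocyte and 4.35 for sperm genes.

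Among genes well above background on at least 1 array of each group, a restriction chosen after values were seen, the largest rises included the eggshell gene cbd-1 (7.75 ± 0.85), the linker histone hil-5 (7.17 ± 0.45), the lectins clec-87 (6.49 ± 0.93) and clec-88 (6.33 ± 0.78), nsph-3.1 (6.14 ± 0.38) and the egg surface gene egg-4 (6.13 ± 0.73). No probe of cbd-1, hil-5, clec-88 or egg-4 was well above background on all 6 arrays, so their sizes and order are uncertain. The RNA interference machinery was called up (adjusted p = 0.00413, 0.657 with an estimated correlation), and of 46 measured genes 19 rose, 8 fell and 19 did not pass the test (20 and 9 adjusted over the list alone, 23 and 3 with the median gene at 0). Its median was 0.57 and turned below 0 (-0.052) on the scale of array medians. The Argonaute gene alg-3 changed by 4.82 ± 0.27 and the RNA-dependent RNA polymerase ego-1 by 4.36 ± 0.33, and the Argonaute gene hrde-1 was at least 7.25-fold higher, all 3 known from the germline.

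Germline signal differed between the arrays labelled nhr-114(RNAi). In replicates 1, 2 and 3 the median of the germline list relative to the 75th percentile was -0.55, 0.76 and 0.30, that of the oocyte list -0.64, 2.34 and 1.64, and that of the sperm list 0.23, 1.24 and 0.53. In glp-1(q224ts) the same medians lay at -3.13, -3.20 and -3.08, at -2.86, -2.92 and -3.06, and at -2.16, -2.26 and -2.13. Somatic markers moved with the groups as well: relative to the median gene the intestine list had a median of -0.28, body wall muscle -0.12, pharynx -0.47 and neurons -0.27, of which only the pharynx stays below 0 with the somatic markers at 0.

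**Figure D2:**
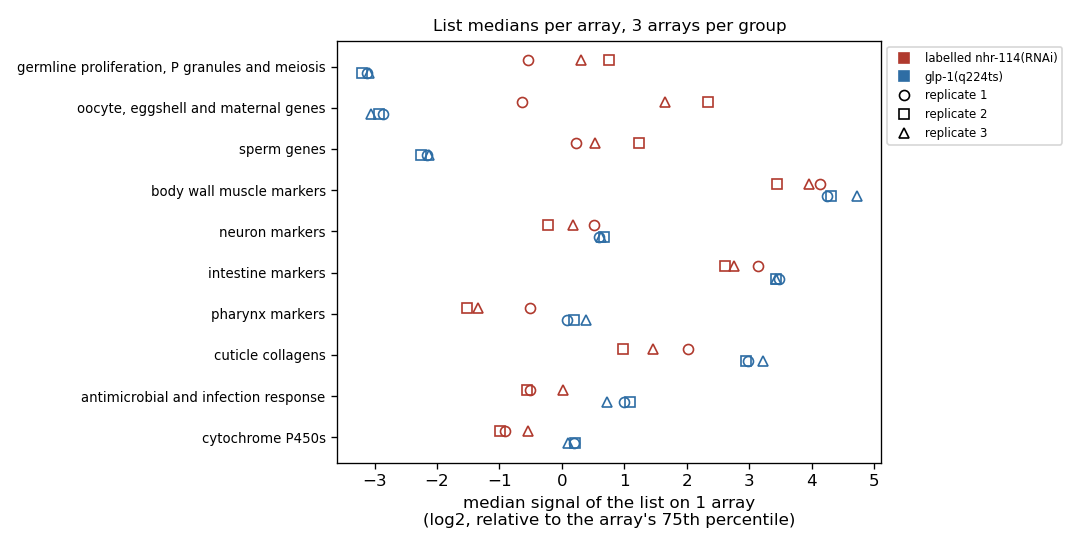
Median signal of 10 gene lists on each array of the first comparison, in log2 units relative to the 75th percentile of the array. Each symbol is 1 array, red for the arrays labelled nhr-114(RNAi) and blue for glp-1(q224ts). The germline, oocyte and sperm medians of every red array lie above those of every blue array, and those of collagens, antimicrobial genes and P450s lie below, as they stand on this scale.

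Structural and defence genes of the soma were lower in the arrays labelled nhr-114(RNAi). Of 135 cuticle collagens, 0 rose, 79 fell and 56 did not pass the test (0 and 85 adjusted over the list alone, 0 and 52 with the median gene at 0) (camera adjusted p = 1.00e-09, 0.657 with an estimated correlation). col-49 changed by -6.13 ± 1.78, col-161 by -5.31 ± 1.27 and col-162 by -4.69 ± 1.06, and copies of this family may share probes. The call of col-49 was lost without glp-1(q224ts) replicates 1, 2 or 3 and without replicates 2 or 3 labelled nhr-114(RNAi), and that of col-161 without glp-1(q224ts) replicate 3. Of 136 antimicrobial and infection-response genes, 2 rose, 88 fell and 46 did not pass the test (2 and 95 adjusted over the list alone, 3 and 57 with the median gene at 0) (adjusted p = 4.67e-10, 0.657 with an estimated correlation). The 3 members named by size were pals genes, a family known from the response to intracellular infection. Of these pals-14 changed by -4.52 ± 0.30, and pals-5 and pals-11 were at least 8.49-fold and 3.70-fold lower. They do not stand for the other pals genes, which were not tested as a family. With bounded genes at their bound the medians were -0.72 for collagens and -0.77 for antimicrobial genes. The C-type lectins went both ways: of 131, 19 rose, 61 fell and 51 did not pass the test (20 and 62 adjusted over the list alone, 20 and 43 with the median gene at 0) (median -0.55, called down, adjusted p = 0.0173, 0.657 with an estimated correlation). The groups overlapped in the median of this list per array (-1.25, -1.42 and -1.06 against -1.06, -1.17 and -1.04). The list median minus the median of the somatic markers of the same array was higher, by 0.48 ± 0.11. This measure, used for lists below as well, compares list medians and not members. The median change of the members stayed below 0 with the somatic markers at 0 (-0.18). clec-123 and clec-91 were at least 74.97-fold and 33.6-fold higher, while clec-258 changed by -5.34 ± 0.74.

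Relative to the median gene 3 detoxification families were lower, while relative to the somatic markers of the same array, a measure chosen after the data were seen, the groups overlapped for each. These differences were -0.35 ± 0.18 for P450s, -0.17 ± 0.15 for glutathione S-transferases and -0.14 ± 0.22 for UDP-glucuronosyl transferases. Of 65 cytochrome P450s, enzymes that oxidise lipids and foreign compounds, 1 rose, 29 fell and 35 did not pass the test (1 and 29 adjusted over the list alone, 2 and 25 with the median gene at 0) (adjusted p = 0.000743). cyp-35B2 changed by -5.20 ± 0.26, cyp-35B1 by -3.74 ± 0.43 and cyp-37B1 by -3.65 ± 0.35. Of 40 glutathione S-transferases, 0 rose, 23 fell and 17 did not pass the test (0 and 24 adjusted over the list alone, 0 and 17 with the median gene at 0) (adjusted p = 1.60e-05), among them gst-19 (-2.82 ± 0.20), gst-14 (-2.15 ± 0.31) and gst-20 (-1.89 ± 0.29). Of 62 UDP-glucuronosyl transferases, 2 rose, 27 fell and 33 did not pass the test (2 and 27 adjusted over the list alone, 3 and 11 with the median gene at 0) (adjusted p = 0.00939), led by ugt-18 (-3.10 ± 0.65), ugt-19 (-1.66 ± 0.45) and ugt-52 (-1.42 ± 0.25). The medians were -0.48, -0.59 and -0.33, and that of the UDP-glucuronosyl transferases turned to 0.039 with the somatic markers at 0. With an estimated correlation the adjusted p was 0.657 for each of the 3 families.

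Genes of the methionine cycle and of propionate breakdown went both ways. Of 16 genes of the methionine and S-adenosylmethionine cycle, 7 rose, 1 fell and 8 did not pass the test (7 and 1 adjusted over the list alone, 7 and 1 with the median gene at 0) (median 0.57, called up, adjusted p = 0.0159, 0.657 with an estimated correlation). The call was lost without replicate 1 labelled nhr-114(RNAi) (adjusted p = 0.0537), and the median turned below 0 (-0.057) on the scale of array medians. Relative to the somatic markers of the same array the list median was higher, by 1.42 ± 0.16, and the groups did not overlap. The S-adenosylmethionine synthetase sams-5 changed by 4.73 ± 0.18 and methionine synthase metr-1 by 2.104 ± 0.28, while cth-1, a cystathionine gamma-lyase, changed by -2.23 ± 0.37. Of 9 measured genes of propionate breakdown, 5 rose, 3 fell and 1 did not pass the test (5 and 3 adjusted over the list alone, 5 and 3 with the median gene at 0). The list was not called (median 0.82, adjusted p = 0.173). Relative to the somatic markers of the same array its median was higher, by 1.32 ± 0.061, and the groups did not overlap. The genes of the vitamin B12-independent propionate shunt acdh-1 (4.83 ± 0.20), ech-6 (2.17 ± 0.19) and hphd-1 (2.04 ± 0.17) rose. The other called members, named after their values were seen, were hach-1 (1.42 ± 0.19), mmaa-1 (0.82 ± 0.18), pcca-1 (-0.58 ± 0.18), mce-1 (-0.46 ± 0.13) and mmcm-1 (-0.59 ± 0.16), and with the somatic markers at 0 the list had 5 higher and 0 lower.

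Amino acid and lipid genes followed. In tryptophan, kynurenine and serotonin metabolism (12 genes, median -0.26), 1 rose, 5 fell and 6 did not pass the test (1 and 6 adjusted over the list alone, 1 and 3 with the median gene at 0). The list was not called (adjusted p = 0.125). The kynurenine monooxygenases parted: kmo-2 changed by 1.63 ± 0.30 and kmo-1 by -0.58 ± 0.16, and cat-4, needed to make serotonin and dopamine, by -0.91 ± 0.17. For other amino acid breakdown (19 genes, median -0.35), 0 rose, 11 fell and 8 did not pass the test (0 and 14 adjusted over the list alone, 0 and 3 with the median gene at 0). The list was called down (adjusted p = 0.00500, 0.657 with an estimated correlation), with hpd-1 at -1.02 ± 0.16, gst-42 at -0.95 ± 0.17 and haly-1 at -0.83 ± 0.27. Both medians turned above 0 with the somatic markers at 0 (0.11 and 0.021), and relative to the somatic markers of the same array the second list was higher, by 0.26 ± 0.12. Of 29 lipases and lipid binding proteins, 1 rose, 16 fell and 12 did not pass the test (1 and 18 adjusted over the list alone, 2 and 12 with the median gene at 0) (median -0.52, adjusted p = 0.00983, 0.657 with an estimated correlation), and relative to the somatic markers the groups overlapped (-0.65 ± 0.42). The lysosomal lipases lipl-1 (-4.10 ± 0.94), lipl-3 (-3.82 ± 0.14) and lipl-2 (-2.74 ± 0.22) fell together. In fatty acid beta-oxidation and ketone metabolism (33 genes), 2 rose, 13 fell and 18 did not pass the test (2 and 13 adjusted over the list alone, 3 and 7 with the median gene at 0), with acs-2 at -3.39 ± 0.39, ech-9 at -2.31 ± 0.30 and cpt-4 at -2.23 ± 0.45. That list was not called (median -0.11, 0.26 with the somatic markers at 0, adjusted p = 0.0506). In fatty acid synthesis, desaturation and elongation (26 genes), 4 rose, 4 fell and 18 did not pass the test (4 and 2 adjusted over the list alone, 4 and 0 with the median gene at 0). The list was not called (median 0.12, below 0 before the shift, adjusted p = 0.763). The elongase genes elo-8 and elo-7 were at least 40.1-fold and 14.7-fold higher, and the citrate lyase acly-2 changed by 1.35 ± 0.22.

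Relative to the median gene, stress and signalling lists were mostly lower. Of 12 hypoxia and sulfide response genes, 0 rose, 9 fell and 3 did not pass the test (0 and 10 adjusted over the list alone, 0 and 7 with the median gene at 0) (median -0.61, adjusted p = 0.000718), with the sulfide quinone oxidoreductase sqrd-1 at -2.74 ± 0.18, cysl-2 at -2.66 ± 0.18 and nhr-57 at -1.80 ± 0.18. For oxidative stress and redox (38 genes), 1 rose, 21 fell and 16 did not pass the test (1 and 21 adjusted over the list alone, 1 and 11 with the median gene at 0) (median -0.29, 0.081 with the somatic markers at 0, adjusted p = 0.00155). The metallothionein mtl-1 changed by -1.93 ± 0.39, cdr-2 by -1.81 ± 0.35 and cdr-1 by -1.46 ± 0.40. Among 44 insulin pathway and DAF-16 target genes, 2 rose, 23 fell and 19 did not pass the test (2 and 25 adjusted over the list alone, 3 and 11 with the median gene at 0) (median -0.44, -0.070 with the somatic markers at 0, adjusted p = 0.000650), and the insulin-like genes ins-37 (5.09 ± 0.26) and ins-20 (-3.47 ± 0.43) moved apart, with dod-3 at -2.68 ± 0.57. Nuclear hormone receptors (195 genes) gave 3 higher, 68 lower and 124 not called (3 and 52 adjusted over the list alone, 3 and 19 with the median gene at 0), with a median of -0.24, or 0.13 with the somatic markers at 0 (adjusted p = 2.84e-05). nhr-19 changed by -1.64 ± 0.18. With an estimated correlation these 4 lists had an adjusted p of 0.657. Relative to the somatic markers of the same array the hypoxia list was lower, by -0.47 ± 0.13, while the groups overlapped for redox genes (0.11 ± 0.078), insulin and DAF-16 genes (0.18 ± 0.15) and nuclear hormone receptors (-0.041 ± 0.17). Of 63 heat shock and unfolded protein response genes, 6 rose, 14 fell and 43 did not pass the test (5 and 12 adjusted over the list alone, 11 and 6 with the median gene at 0). The list was not called (median 0.20, below 0 before the shift, adjusted p = 0.818). dnj-26 was at least 9.18-fold higher, dnj-28 changed by 2.42 ± 0.38 and abu-1 by -1.82 ± 0.53.

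Somatic markers were called down in part. Of 22 intestine markers, 0 rose, 8 fell and 14 did not pass the test (0 and 6 adjusted over the list alone, 1 and 3 with the median gene at 0) (adjusted p = 0.0293), with the intermediate filaments ifc-2 (-0.92 ± 0.28) and ifb-2 (-0.86 ± 0.31) and the ferritin ftn-1 (-0.92 ± 0.40) leading. Of 24 body wall muscle markers, 0 rose, 6 fell and 18 did not pass the test (0 and 3 adjusted over the list alone, 0 and 1 with the median gene at 0) (adjusted p = 0.0293), with unc-22 at -0.65 ± 0.17, myo-3 at -0.64 ± 0.27 and unc-89 at -0.53 ± 0.19. Of 24 neuron markers, 0 rose, 10 fell and 14 did not pass the test (0 and 8 adjusted over the list alone, 0 and 6 with the median gene at 0) (adjusted p = 0.00939), with snb-1 at -0.85 ± 0.20, unc-10 at -0.75 ± 0.17 and ida-1 at -0.72 ± 0.17. Of 16 pharynx markers, 0 rose, 8 fell and 8 did not pass the test (0 and 8 adjusted over the list alone, 0 and 4 with the median gene at 0) (adjusted p = 0.0171), with abu-11 at -2.21 ± 0.66, abu-8 at -1.76 ± 0.69 and phat-2 at -1.08 ± 0.32. With an estimated correlation the adjusted p was 0.657, 0.727, 0.657 and 0.657. The intestine, muscle and neuron medians turned above 0 with the somatic markers at 0 (0.086, 0.24 and 0.096), a setting that centres on these lists. The calls of the intestine and muscle lists were lost without replicate 2 labelled nhr-114(RNAi) or glp-1(q224ts) replicate 3 (adjusted p up to 0.0702 and 0.0867). For markers of the somatic gonad, vulva and spermatheca (19 genes), 1 rose, 4 fell and 14 did not pass the test (1 and 3 adjusted over the list alone, 1 and 1 with the median gene at 0), and the list was not called (median -0.062, 0.30 with the somatic markers at 0, adjusted p = 0.203). inx-14, a gap junction gene also used by germ cells, changed by 3.10 ± 0.50 and fos-1 by -0.50 ± 0.18, while the Notch ligand lag-2 was at least 1.34-fold lower.

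Housekeeping lists held single members that rose strongly. Of 76 ribosomal protein genes, 3 rose, 0 fell and 73 did not pass the test (2 and 0 adjusted over the list alone, 3 and 0 with the median gene at 0). The list was not called (median 0.11, below 0 before the shift, adjusted p = 0.818). In 3 settings camera called it up: quantile normalization (adjusted p = 1.56e-05), the authors' value table (2.67e-06) and the somatic markers at 0 (0.00149). rpl-42 was at least 26.9-fold higher, rpl-11.1 changed by 2.31 ± 0.21 and rps-14 by 1.36 ± 0.35. In the mitochondrial respiratory chain (51 genes), 3 rose, 7 fell and 41 did not pass the test (3 and 1 adjusted over the list alone, 3 and 1 with the median gene at 0) (median -0.18, mean 0.069, called down, adjusted p = 0.0313, 0.747 with an estimated correlation). Its median turned to 0.19 with the somatic markers at 0, and the call was lost without replicate 2 labelled nhr-114(RNAi) or glp-1(q224ts) replicate 3 (adjusted p up to 0.120). cyc-2.2 (5.09 ± 0.29) and ucr-2.3 (4.74 ± 0.40) rose while sdha-1 changed by -0.93 ± 0.22. Of 32 histone genes, 5 rose, 1 fell and 26 did not pass the test (5 and 0 adjusted over the list alone, 7 and 0 with the median gene at 0). The list was not called (median 0.21, below 0 before the shift, adjusted p = 0.241). his-70 and his-68 were at least 42.5-fold and 20.1-fold higher and his-74 changed by 4.55 ± 0.39, with copies that probes may not separate. Of 41 proteases of the gut lumen and lysosome, 3 rose, 21 fell and 17 did not pass the test (3 and 24 adjusted over the list alone, 3 and 14 with the median gene at 0) (median -0.41, adjusted p = 0.0155, 0.657 with an estimated correlation), with cpr-2 at -4.90 ± 0.21 and the trypsin-like try-7 and try-16 at least 8.57-fold and 13.2-fold higher. Among 93 transporters of xenobiotics and nutrients, 7 rose, 28 fell and 58 did not pass the test (7 and 26 adjusted over the list alone, 13 and 10 with the median gene at 0) (median -0.16, mean 0.096, not called, adjusted p = 0.0728). The median turned to 0.21 with the somatic markers at 0, and snf-5, snf-2 and snf-7 were at least 36.7-fold, 16.9-fold and 4.78-fold higher. None of the 6 vitellogenins was called (median -0.012, adjusted p = 0.521), and vit-5 had the smallest p (-0.086 ± 0.21). The median of the list was above 0 with quantile normalization, the authors' value table and the somatic markers at 0. Of 7 early embryo genes, 0 rose, 1 fell and 6 did not pass the test (0 and 1 adjusted over the list alone, 0 and 1 with the median gene at 0) (median -0.069, 0.30 with the somatic markers at 0, adjusted p = 0.391), the fallen one being pha-4 (-0.68 ± 0.16).

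Of 110 called genes named for this comparison, leaving out 1 array ended 0, 3 and 8 calls (replicates 1, 2 and 3 labelled nhr-114(RNAi)) and 8, 10 and 17 calls (glp-1(q224ts) replicates 1, 2 and 3). The genes affected by leaving out an array were ugt-19, haly-1, ftn-1, ifc-2, ifb-2, myo-3, unc-89, abu-1, abu-8, abu-11, phat-2, fos-1, col-49, col-161, cdr-1, rps-14, cyp-35A1 and clec-230. With the median gene at 0, 7 of the 110 calls were lost (haly-1, ftn-1, ifb-2, myo-3, unc-89, abu-8 and fos-1). With the somatic markers at 0, 20 were lost: the same 7 and ugt-52, kmo-1, pha-4, ifc-2, unc-22, snb-1, unc-10, ida-1, lag-2, cdr-1, sdha-1, cyp-35A1 and lbp-8. Among the other settings, ftn-1, myo-3 and rps-14 were lost with quantile normalization, these 3 and snf-7 with the authors' value table, and these 3 and abu-8 without the filter on dim probes. The replicate block ended the calls of ftn-1 and rps-14, and the fit of all 12 arrays those of myo-3 and phat-2. normexp and the scale of array medians each ended that of rps-14.

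A small set of genes, among them cytochrome P450s and a lipid binding protein, was higher in wild type animals with added tryptophan, and none was called without wild type replicate 3. The cytochrome P450 genes cyp-35A3 (3.00 ± 0.21, 8.01-fold), cyp-35A1 (2.93 ± 0.31) and cyp-35A4 (2.75 ± 0.18) rose, as did the lipid binding protein lbp-8 (3.25 ± 0.21, 9.52-fold) and the C-type lectin clec-169 (4.79 ± 0.43, 27.8-fold, log2 values with SE, n = 3 arrays per group). The glucuronosyl transferase ugt-34 changed by 4.35 ± 0.49 and gba-2, a glucosylceramidase, by 3.53 ± 0.32. ugt-34 and cyp-35A1 had no probe well above background on all 6 arrays. Their wild type means (-6.08 and -6.05) lay near the lowest signal well above background on those arrays (-6.14, -6.31 and -5.98). The sizes of these changes are therefore uncertain. The fit called 20 genes higher and 1 lower of 15562 tested, the lower one being clec-230 (-2.39 ± 0.24, limma adjusted p = 0.0224). At an unadjusted p under 0.05, 359 genes were higher and 316 lower, and the groups did not overlap for 1359 genes (8.73%, where chance gives 10%). nhr-114 differed by -0.40 ± 0.19 and glp-1 by -0.098 ± 0.17, neither called (adjusted p = 0.995 for both).

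Adjusted p values of these genes were 0.00526 for lbp-8 and cyp-35A4, 0.00602 for cyp-35A3, 0.0147 for clec-169 and gba-2, 0.0128 for the infection-response gene irg-6 (2.58 ± 0.21), 0.0297 for cyp-35A1, 0.0341 for ugt-34, ugt-9 (2.29 ± 0.26) and F58B4.5 (2.03 ± 0.23), 0.0183 for ugt-21 (1.94 ± 0.19) and 0.0446 for clec-206 (2.51 ± 0.30). The other called genes, named because so few passed and after their values were seen, were cyp-13A5 (2.63), cyp-29A3 (1.54), bigr-1 (2.39), C40H1.8 (2.98), T16G1.6 (2.09), T16G1.4 (1.97), R02C2.7 (2.07) and srw-96, which was below background in wild type and at least 1.45-fold higher. Every kept probe of each called gene had the sign of its gene.

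The count with Trp rests on single arrays. It was 0 without wild type replicate 3, 3 higher and 0 lower without Trp replicate 2, 4 and 1 without Trp replicate 3, 4 and 0 without wild type replicate 1 or 2, and 1.1e+02 (rounded) and 15 without Trp replicate 1. Without the filter on dim probes 3 genes were higher and 0 lower. Of 13 calls named by the fixed rule, only lbp-8, cyp-35A3 and cyp-35A4 were kept without that filter or without Trp replicate 2. Kept were these and clec-169 without Trp replicate 3, these 3 and ugt-34 without wild type replicate 1, and these 3 and cyp-35A1 without wild type replicate 2. normexp ended the calls of cyp-35A1, ugt-21, clec-206 and clec-230, and the fit of all 12 arrays those of ugt-9, clec-206, clec-230 and gba-2. The replicate block ended those of ugt-9, ugt-21, clec-230 and F58B4.5, and the somatic markers at 0 that of F58B4.5.

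**Figure D3:**
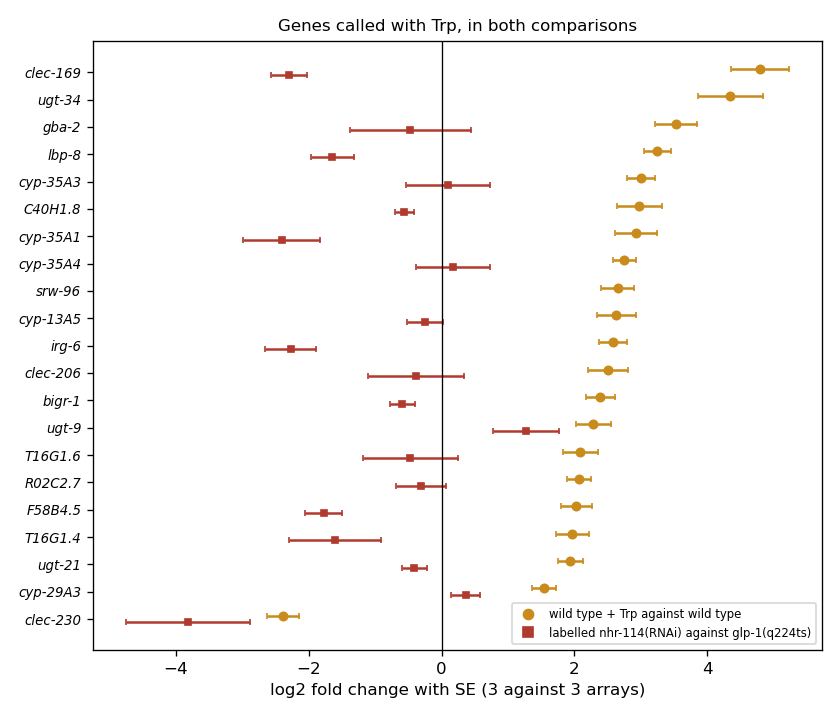
Log2 fold change with SE of the 21 genes called with Trp (circles, Trp against wild type) and of the same genes where tested in the first comparison (squares, arrays labelled nhr-114(RNAi) against glp-1(q224ts), before the shift by the median gene), 3 arrays per group. The value of srw-96 is the fitted one, and only its bound is a measurement. No probe of ugt-34 or cyp-35A1 was well above background on all 6 arrays, so their values rest in part on signal near background. With Trp 20 genes lie above 0 and clec-230 below.

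With Trp 5 lists were called up and 5 down. Of 62 cytochrome P450s 5 rose, 0 fell and 57 did not pass the test (19 and 0 adjusted over the list alone), and the list was called up (median 0.26, camera adjusted p = 3.28e-17, 0.363 with an estimated correlation). For 61 UDP-glucuronosyl transferases, 3 rose, 0 fell and 58 did not pass the test (13 and 0 adjusted over the list alone) (median 0.38, called up, adjusted p = 9.33e-18, 0.363 with an estimated correlation). None of 38 glutathione S-transferases was called, and 4 were higher adjusted over the list alone, with gst-5 at 1.85 ± 0.29 (median 0.17, list called up, adjusted p = 4.64e-07). Nuclear hormone receptors (200 genes, median 0.019) and lipases and lipid binding proteins (31 genes, median 0.10) were also called up (adjusted p = 0.00585 and 0.0368). The first had no called member, 6 higher and 1 lower adjusted over the list alone, and nhr-142 at 1.29 ± 0.21, and the second had lbp-8, with 3 higher adjusted over the list alone. Lists called down had no called member, and 0 adjusted over the list alone. They were sperm genes (median -0.48, adjusted p = 4.44e-08, ssp-16 -0.72 ± 0.28), cuticle collagens (-0.35, 3.80e-08, col-149 -1.43 ± 0.38), ribosomal proteins (-0.22, 8.86e-06, rps-14 -0.46 ± 0.19), histones (-0.19, 0.0288, his-25 -0.51 ± 0.22) and fatty acid synthesis, desaturation and elongation (-0.17, 0.0486, elo-8 -0.46 ± 0.19). With an estimated correlation the adjusted p of these lists other than the P450s and UDP-glucuronosyl transferases was 0.895, and no list was called by an estimated correlation or by fry.

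Single arrays decide part of these list calls. Without wild type replicate 3, 5 lists were called, and the calls of sperm genes, ribosomal proteins, histones, nuclear hormone receptors, lipases and fatty acid synthesis were lost. Without Trp replicate 1 the collagen, ribosomal protein, histone, lipase and fatty acid synthesis calls were lost, without Trp replicate 2 those of nuclear hormone receptors and fatty acid synthesis, without Trp replicate 3 that of lipases, and without wild type replicate 2 that of fatty acid synthesis. With these arrays left out the adjusted p reached 0.126 for sperm genes, 0.857 for collagens, 0.423 for ribosomal proteins, 0.689 for histones and for nuclear hormone receptors, 0.178 for lipases and 0.596 for fatty acid synthesis.

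The lists below were not called with Trp, and each is given with its median, its adjusted p and the member of smallest p. Germline genes had -0.092 and 0.752 with syp-3 at 0.49 ± 0.38, oocyte genes -0.098 and 0.472 with egg-3 at -0.21 ± 0.17, and early embryo genes 0.17 and 0.116 with pes-10 at 0.59 ± 0.21. Tryptophan, kynurenine and serotonin metabolism had 0.031 and 0.0985 with kmo-1 at 0.55 ± 0.19, other amino acid breakdown -0.0055 and 0.565 with gst-42 at 0.22 ± 0.19, the methionine cycle -0.23 and 0.0654 with sams-5 at -0.58 ± 0.28, and propionate breakdown -0.14 and 0.326 with pccb-1 at -0.43 ± 0.39. Vitellogenins had -0.20 and 0.385 with vit-3 at -0.24 ± 0.28. Intestine markers had -0.15 and 0.589 with pgp-1 at 2.15 ± 0.40, which also led the transporters (-0.067 and 0.586). Muscle markers had -0.16 and 0.174 with tni-3 at -0.26 ± 0.23, pharynx markers -0.17 and 0.565 with tnc-2 at 0.32 ± 0.17, neuron markers -0.13 and 0.596 with unc-64 at 0.23 ± 0.17, where 1 of 3 probes has the other sign, and gonad markers -0.029 and 0.949 with lin-11 at -0.49 ± 0.33. Beta-oxidation had -0.040 and 0.565 with ech-1.1 at -0.77 ± 0.22, heat shock -0.056 and 0.846 with hsp-43 at -0.40 ± 0.18, redox genes 0.0032 and 0.194 with cdr-4 at 1.37 ± 0.22, hypoxia genes -0.12 and 0.421 with sqrd-1 at -0.38 ± 0.21, and insulin and DAF-16 genes -0.18 and 0.153 with dod-3 at -1.196 ± 0.26. The respiratory chain had -0.11 and 0.328 with cox-15 at -0.21 ± 0.16, gut proteases -0.13 and 0.565 with asp-15 at 1.08 ± 0.23, RNA interference machinery -0.024 and 0.846 with alg-4 at -0.67 ± 0.37. C-type lectins had -0.045 and 0.565, with 2 called higher and 1 lower, and antimicrobial genes -0.018 and 0.586 with irg-6 called. Adjusted over the list alone, 9 C-type lectins were higher and 5 lower, 1 antimicrobial gene, 1 intestine marker and 1 redox gene were higher, and no member of the other lists of this paragraph passed. For other amino acid breakdown, C-type lectins, antimicrobial genes, RNA interference machinery and transporters the median was below 0 while the set test pointed up.

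Both comparisons called 8 genes of 13908 tested in both. cyp-35A1, clec-169, irg-6, F58B4.5 and lbp-8 were lower in the arrays labelled nhr-114(RNAi) (-2.14, -2.03, -2.01, -1.51 and -1.38 relative to the median gene) and higher with Trp. In this pair of directions 7 genes were shared where 4.84 are expected from the counts (two-sided Fisher's exact p = 0.287, adjusted over 4 direction pairs 0.382). clec-230 was lower in both (-3.55 ± 0.93 relative to the median gene in the first). Higher in both were 0 genes, with 3.40 expected (Fisher's exact p = 0.0346, adjusted 0.138). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.12 and a Spearman rho of -0.0073. Of 19 genes called with Trp and tested in both, 14 lay below the median gene in the first comparison, as did 50.4% of all genes tested in both. Array rows run the opposite way in the 2 comparisons, so opposite signs cannot be told apart from array row. The comparisons lie on different slides, so a difference between them cannot be told apart from slide.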

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

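The settings with the median gene at 0 and with the somatic markers at 0 were chosen after the data were seen, and the other settings before. In the first comparison nhr-114 was called higher in every setting run, with log2 differences between 2.21 and 3.50. The counts changed by more than 1.5 times in some settings: 7956 genes were lower on the scale of array medians, 1882 higher among probes well above background on all 6 arrays (where fewer genes are tested), 1837 lower with the median gene at 0, 5450 higher and 910 lower with the somatic markers at 0, and 1490 lower at a fold of at least 2, which is the stricter threshold itself. Leaving out 1 array gave 2015 to 5024 lower genes. The number of lists called was 0 with an estimated correlation and 25 by fry. Where the construction of a setting does not show it, the cause was not tested.

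Set tests of the first comparison that changed direction had these adjusted p values: with quantile normalization vitellogenins 0.336, beta-oxidation 0.997, heat shock genes 0.229 and ribosomal proteins 1.56e-05, with the authors' value table vitellogenins 0.345, beta-oxidation 0.980, heat shock genes 0.234 and ribosomal proteins 2.67e-06, with the somatic markers at 0 vitellogenins 0.920, heat shock genes 0.413 and ribosomal proteins 0.00149, without the filter on dim probes early embryo genes 0.722, with normexp heat shock genes 0.894 and ribosomal proteins 0.894, with probes well above background on all 6 arrays heat shock genes 0.874 and ribosomal proteins 0.711, with the median gene at 0 heat shock genes 0.746 and ribosomal proteins 0.378. Ribosomal proteins passed the threshold in the new direction in 3 of these settings, and their adjusted p over all alternatives ran from 2.67e-06 to 0.971. Over arrays left out in turn, lists with a change of direction ranged as fatty acid synthesis 0.214 to 0.860, heat shock genes 0.605 to 0.917 and ribosomal proteins 0.111 to 0.660. The log2 change of vit-5, not called in the main fit, was 0.000910 with quantile normalization and 0.28 with the somatic markers at 0, both without the shift by the median gene. It was called lower in 1 of 18 settings (limma adjusted p = 0.0205). The cause was not tested.

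With Trp, genes higher numbered 47 on the scale of array medians, 3 without the filter on dim probes, 53 with all 12 arrays in 1 fit, 36 with trend and 32 with the somatic markers at 0. Genes lower numbered 0 with normexp, 2 with quantile normalization, 5 on the scale of array medians, 0 without the filter, 4 with the mean of the probes, 8 with all 12 arrays and 2 with the somatic markers at 0. Leaving out 1 array gave 0 (without wild type replicate 3, where limma also called 0 lower) to 1.1e+02 (rounded, without Trp replicate 1) higher, 0 to 15 lower and 5 to 10 lists called. No list was called with an estimated correlation (0) or by fry (0). Genes called in both comparisons numbered 30 on the scale of array medians, 1 without the filter, 5 with probes well above background on all 6 arrays, 28 with all 12 arrays, 15 with trend, and 0 to 61 with 1 array left out. The cause was not tested.

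Set tests with Trp that changed direction, none of them past the threshold in these settings, had these adjusted p values: with normexp other amino acid breakdown 0.955 and RNA interference machinery 0.856, with quantile normalization vitellogenins 0.970, germline genes 0.859, oocyte genes 0.276, heat shock genes 0.905, RNA interference machinery 0.998 and respiratory chain 0.661, with the authors' value table vitellogenins 0.972, germline genes 0.928, oocyte genes 0.284, heat shock genes 0.939, RNA interference machinery 0.972 and respiratory chain 0.655, with all 12 arrays in 1 fit germline genes 0.936, with the somatic markers at 0 germline genes 0.976, gonad markers 0.976 and heat shock genes 0.976, with the replicate number as a block gonad markers 0.999 and heat shock genes 0.999, with the median gene at 0 gonad markers 0.984, by fry C-type lectins 0.965, antimicrobial genes 0.965, RNA interference machinery 0.858 and transporters 0.953, without the filter on dim probes heat shock genes 0.932. Over arrays left out in turn, lists with a change of direction ranged as vitellogenins 0.0525 to 0.735, germline genes 0.0603 to 0.886, oocyte genes 0.0611 to 0.864, intestine markers 0.281 to 0.735, body wall muscle markers 0.00515 to 0.764, pharynx markers 0.00331 to 0.569, neuron markers 0.0501 to 0.777, gonad markers 0.373 to 0.893, C-type lectins 0.206 to 0.879, antimicrobial genes 0.0855 to 0.735, heat shock genes 0.0471 to 0.924, insulin and DAF-16 genes 0.0501 to 0.983, RNA interference machinery 0.0162 to 0.991, respiratory chain 0.0599 to 0.748, histones 4.48e-05 to 0.689, gut proteases 0.187 to 0.886 and transporters 0.193 to 0.900. After a change of direction, pharynx markers (0.0404) and RNA interference machinery (0.0162) passed the threshold without Trp replicate 1. vit-3, not called, ranged from -0.42 to 0.043. The cause was not tested.

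Over all alternatives, 1857 of 1952 values of named genes kept direction and side of the threshold in the first comparison and 666 of 754 with Trp, while 90 and 73 lost the call and 3 and 14 gained it. For set tests 580 and 563 of 680 per comparison kept both, 64 and 49 lost the call and 13 and 11 gained it.

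Arrays with the same replicate number did not vary together. Deviations from the group mean correlated at -0.037, -0.064 and 0.063 for the same number in the first comparison and at -0.26, -0.36 and 0.27 with Trp, where pairs of different numbers reached 0.49, so the fits are unpaired. With the replicate number as a block, 2677 genes were higher and 3040 lower in the first comparison and 18 and 0 with Trp, which kept 12 of the 21 calls, and 5 were called in both. Every planned setting was run, normexp on the median spot signal as a substitute for the mean signal. Signal over background limits the folds of 829 called genes of the first comparison, below background in glp-1(q224ts), to bounds.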

Other observations

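The tests of families, exchanged labels, germline RNA, trigger RNA, dilution, the bright array and array row were chosen after the result was seen, and the test of scaling uses a setting chosen after the data were seen. Gene families beyond the fixed lists were counted by the letters of their symbols, 120 families with at least 10 tested members, in the first comparison (1-sided Fisher's exact test against all tested genes, adjusted over families and directions). Families with more higher genes than the 20.4% of all genes were nspd 10 of 10 (adjusted p = 7.24e-06), bath 15 of 24 (0.000328), the nuclear pore genes npp 15 of 25 (0.000570), the RNA polymerase II genes rpb 9 of 11 (0.000655) and cdc 8 of 14 (0.0496). Families with more lower genes than the 26.9% of all genes follow, each with its count lower with the median gene at 0 and with the somatic markers at 0: the neuropeptide genes nlp 49 of 64 (26 and 4) and flp 24 of 30 (6 and 0), nssp 52 of 79 (28 and 13), fbxa 54 of 117 (32 and 18), nspb 9 of 11 (9 and 8), ttr 25 of 50 (15 and 5), srlf 11 of 16 (6 and 3) and nspg 9 of 12 (4 and 1). Their adjusted p values were 3.68e-14, 1.55e-07, 5.89e-11, 0.000275, 0.00616, 0.00981, 0.0123 and 0.0140. Fisher's test takes the genes of a family as independent. Members can move together or share signal on a probe, so the p values of both directions may be too small. Over all 14773 genes, 1837 and 910 were lower in these 2 settings.

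nhr-114 signal was higher in the arrays labelled nhr-114(RNAi) than in glp-1(q224ts). An exchange of the labels of the 2 groups is argued against by the germline list, of which 92.1% was called higher in these arrays, where glp-1(q224ts) animals would have almost no germ cells. RNA of germline cells may carry nhr-114: these arrays lay 1.54 ± 0.76 (SE) above wild type, which has a full germline, but the groups lie on different slides and the value cannot decide, and replicate 1, with the lowest germline median (-0.55), had the highest nhr-114 signal (2.64). Trigger RNA read by the probes stays open as well, since the 3 probes differed by at most 0.038 (SE of a probe 0.62) and the region of the trigger is not known. A lack of knockdown, or a rise of the gene's own transcript in response to it, was not tested.

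Cuticle collagens, antimicrobial genes and cytochrome P450s were lower in the arrays labelled nhr-114(RNAi) in all 7 scalings compared. Dilution of somatic RNA by germline RNA would lower all somatic lists alike. Relative to the somatic markers of the same array, the collagens were lower by a log2 difference of -0.94 ± 0.17. The antimicrobial genes were lower by -0.65 ± 0.25, and the P450s differed by -0.35 ± 0.18. Among the marker lists themselves, the pharynx was lower by -0.71 ± 0.23 and its groups did not overlap. The groups overlapped for intestine (0.024 ± 0.13), body wall muscle (0.048 ± 0.098) and neurons (0.16 ± 0.11). By this measure of list medians the marker lists thus did not move alike, and the pharynx could not be told apart from the antimicrobial genes within the SE. The median change of members had another order: relative to the median gene it was -0.47 for the pharynx and -0.84 for both collagens and antimicrobial genes. The test therefore does not decide on dilution for collagens, antimicrobial genes or P450s. With the median gene at 0, 52 of 79 collagens, 57 of 88 antimicrobial genes and 25 of 29 P450s were still called lower. At that shift this argues against scaling to the 75th percentile as the whole cause. With the somatic markers at 0, a larger shift, the medians were -0.47 for collagens, -0.47 for antimicrobial genes and -0.11 for P450s. That leaves scaling open for the P450s. A candidate explanation is a difference between these sterile animals in the soma itself. The design sets the RNA interference against the glp-1 mutation, so it cannot assign that difference to either, and it was not tested.

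For the genes called with Trp, the bright Trp replicate 1 is argued against as the source, since 122 genes were called over all genes without that array and 21 with it. An effect of the array row would have opposite signs in the 2 comparisons. If it were equal on both slides, the sum of both log2 changes would lie near 0. The median sum over the 18 genes higher with Trp and tested in both was 1.85 ± 0.30 (SE). That SE is over genes, which can move together. The genes were also picked for their rise with Trp, which lifts the sum. The value therefore does not decide on an equal row effect. For 4 genes the sum lay within 2 SE of 0 (cyp-35A1, irg-6, F58B4.5 and T16G1.4). A row effect of this slide alone stays open for every gene. The calls are fragile to single arrays, with 0 genes higher without wild type replicate 3 (limma). Tryptophan, which the design names, stays among the open explanations, and a response of the bacteria to it could not be told from a response of the animals.

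Other divisions of the 6 arrays of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. In the first comparison the real split called 6979 genes and the highest other 0, so 1 of 10 splits gave as many, and for lists 3 of 10 gave as many as the real 23, the highest other being 24. With Trp the real split called 21 genes and the highest other 0, again 1 of 10, and for lists 7 of 10 splits gave as many as the real 10, the highest other being 17.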
